A study of Mus musculus with 18 samples.

How the data were processed

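Histone variant H3.3 was measured by crosslinking chromatin immunoprecipitation with sequencing (ChIP-seq) in mouse nucleus accumbens. The labels give 18 libraries, 9 of H3.3 ChIP and 9 of Input, in 3 conditions with 3 ChIP and 3 Input libraries each. Each library pooled the bilateral nucleus accumbens of 5 animals, per the labels' protocols, which call the replicates biological. Libraries were made with the Illumina TruSeq ChIP kit, per the labels' protocols.

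Bowtie2 2.2.0, SAMtools 0.1.19 and the mouse genome build mm10 are named in the submitters' processing notes. The data analysed here are 2 tables of differential sites that the authors deposited, 1 for susceptible re-exposed mice against controls and 1 for acute stress against controls. The table names give diffReps, windows of 250 base pairs and a p threshold. The largest p listed was 9.32e-05 in the susceptible table and 9.98e-05 in the acute table, both under 0.0001. The diffReps version, its test, its normalisation and its read filters are not given in the sources used here.

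Each site in the deposited tables has 5 kinds of value. The count columns hold normalised read counts, 1 per library, as the authors deposited them. The average columns hold the mean coverage signal of a group in normalised reads, per the file headers. The enrichment columns hold a ratio for each group, per the file headers, and what this ratio is relative to is not stated in the sources used here. The log2 fold change of the stress mean over the control mean was deposited by the authors. The p-value and an adjusted p-value per site were deposited by the authors, and their test is not stated. The tables also give a gene, a transcript and a genomic class for sites in gene bodies and promoters. Exon and intron positions are not given in the sources used here.

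The count cells held 3 susceptible and 2 control libraries in the susceptible table, and 2 acute stress and 2 control libraries in the acute table. The labels describe 3 ChIP libraries per condition, and which of them each position in a cell holds is not given in the sources used here, so libraries are named by their position. The planned tests assumed a comparison table without values per library or a table of raw counts. The values per library turned out to be normalised and to cover only the listed sites, so no count model was fitted and the authors' test per site was kept as the main one. Within each library the values were whole multiples of a single step, the value of 1 read. Dividing by that step gave whole reads for 99.9% to 100% of the values per library, within a tolerance of 0.011. On simulated tables the recovered reads were right for 100% of values in each library.

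The recovered reads were used for an added check, a two-sided exact binomial test of the stress reads among all reads of a site given the libraries' relative depths. It covers counting error only, not the spread between animals or libraries. At the threshold of 0.0001, it recovered 0.5% of simulated sites with a 2-fold change, 11% with a 4-fold change and 25.5% with an 8-fold change at the depths of the susceptible comparison. At the depths of the acute comparison it recovered 0%, 11.5% and 26%. No unchanged simulated site was called. The simulated control level was each listed site's mean over the libraries of both groups. That lies below the control mean at the lower sites, so recovery at their control level is understated. Folds of pooled reads are given with exact Clopper-Pearson 95% intervals, which also cover counting error only. Means and SDs are over the normalised counts of the libraries in the cell. With 2 or 3 libraries per group, a two-sided exact permutation test of a single site across libraries cannot go below p = 0.2 in the susceptible comparison and p = 0.333 in the acute one, so no such test is reported.

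The split between higher and lower sites was tested with a two-sided exact binomial test over sites and a two-sided exact sign test over the 19 autosomes. The share of lower sites has a Wilson 95% interval. Differences between the comparisons and between genomic classes were tested with two-sided Fisher exact tests, with Benjamini-Hochberg adjustment over the classes. The 3 promoter classes were pooled, and pericentromeric and subtelomeric sites were pooled as chromosome ends. Sites of the 2 tables were called shared where they overlapped by at least 1 base pair. The number of shared sites was set against 1000 random placements of the acute sites on their own chromosomes, with a one-sided permutation p. The share of sites in protein-coding genes was set against 1000 random placements with a two-sided p. A planned simulation set unchanged groups against shared controls, with levels drawn from the listed sites' means (20 draws of 39770 regions). It called a mean of 0.3 lower susceptible and 0.2 lower acute sites per draw, and 0 lower sites were shared. With so few calls it gave no usable value for the overlap that shared controls alone would give. All 300 overlaps planted in simulated tables were found.

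Genes were taken from the tables for sites in a gene body or promoter, and 632 of 635 names in the susceptible table and 501 of 502 in the acute table matched the RefSeq annotation of GRCm38.p6, the assembly that mm10 denotes. The tabulated transcripts lay inside the RefSeq gene of the same name for 98.4% and 97.0% of the matched genes. Before the data were examined, 21 gene lists were fixed: immediate early genes, medium spiny neuron markers, striatal interneuron markers, glutamate receptors, GABA receptors, monoamine and peptide receptors, synaptic adhesion, postsynaptic scaffold, presynaptic release, voltage-gated channels, axon guidance, glucocorticoid and stress signalling, neurotrophic signalling and plasticity, H3.3 with its chaperones, chromatin regulators, markers of oligodendrocytes, oligodendrocyte precursors, astrocytes, microglia and endothelial or mural cells, and housekeeping genes. List members with a site were counted against 10000 random lists of protein-coding genes matched on gene length (within 100 ranks), with a two-sided permutation p and Benjamini-Hochberg adjustment over the lists. In simulated tables this called 0 of 210 lists without an effect, against 50 of 210 when length was not matched, and it called a planted adhesion list in 9 of 10 runs. The planted list was the largest, with 51 members, and its members were hit more often than their length gives. No other list was planted, so the power for smaller lists is not known. A count adjusted over the list alone cannot be given, because the tables list only sites past the threshold.

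The genes named in the text followed a rule fixed before the data were examined. In each table it takes, among sites in protein-coding genes, the 8 higher and 8 lower sites with the smallest deposited p (1 per gene), the 3 genes with the most sites, up to 3 members of each list, and up to 8 genes with a site in both tables. Further members of the lists are named without levels as examples, picked after the lists were counted, and other genes are named where the text says so. The lower sites of the GABA receptor list and some sites in other genes are not reported here.

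Alternatives fixed in advance were a p threshold of 1e-05, an adjusted p of 0.05, an absolute log2 fold change of 1, at least 50 reads per site, chromosomes 1 to 19, merging within 1 kb, other overlap rules, lists not matched on length, and leaving out each library. The counting test, a minimum enrichment ratio of 1 in the higher group, and complete separation of the libraries were added after seeing the data. Enrichment ratios listed as infinite were counted as at least 1. Input libraries have no values of their own in the tables and were not analysed here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.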

Results

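H3.3 ChIP-seq was carried out on the nucleus accumbens, a ventral striatal region of the brain's reward circuit, in C57Bl/6J mice. H3.3 is the variant of histone H3 that is placed into chromatin outside DNA replication, so it can be exchanged in cells that no longer divide, such as neurons. Control mice were taken from their home cage. Acutely stressed mice met an aggressor for 5 min and were then housed next to it for 55 min. Susceptible mice had gone through chronic social defeat, a model in which repeated encounters with an aggressor leave part of the animals socially avoidant. They were scored in a social interaction test at 48 h and met the same 1 h of stress again. Animals were killed at day 28 after the last defeat. No group of susceptible mice without the renewed stress was among these libraries. Differences between susceptible mice and controls therefore cannot be assigned to the re-exposure rather than to the earlier defeat or the selection as susceptible.

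Each of the 3 conditions had 3 ChIP and 3 Input libraries, 18 in all, and each library pooled 5 animals. The values below come from 2 lists of differential H3.3 sites that the authors derived against the control condition. The susceptible list gave normalised read counts for 3 susceptible and 2 control libraries at 1286 sites, and the acute list for 2 acute stress and 2 control libraries at 1014 sites. At the 18 sites with the same coordinates in both lists the control reads were equal in 18, so the 2 comparisons shared their control libraries. Sites had a median length of 275 bp and 300 bp. They held a median of 40 reads over 5 libraries (range 27 to 166) and of 37 reads over 4 libraries (range 21 to 126). In the susceptible list 1 read was worth 1.63, 0.828 and 1.47 normalised counts in the susceptible libraries and 0.918 and 0.534 in the control libraries. In the acute list it was worth 0.951 and 1.43 in the acute stress libraries and 1.08 and 0.657 in the control libraries. Total library sizes are not given in the sources used here, so these steps are the only measure of relative depth. By the steps, the second control library was 1.72 times as deep as the first in the susceptible list and 1.65 times in the acute list. The steps thus also carry the normalisation of each list. The counting test takes its depths from them and is no check on that normalisation.

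The first comparison asked where H3.3 differed from controls when mice susceptible to chronic defeat met the stressor again. H3.3 was lower than in controls at nearly all sites that differed. The authors' deposited table lists 1255 lower and 31 higher sites, a lower share of 97.6% (95% Wilson interval 96.6 to 98.3%). At the lower sites the median of the group means was 2.18 normalised counts in susceptible mice and 11.8 in controls, with a median log2 fold change of -2.42 in the authors' deposited table. The smallest control values at any lower site were 10.1 and 9.61 in the 2 control libraries, close to that control median. At the higher sites these medians were 13.4 and 3.82, with a median log2 fold change of 1.99 in the authors' deposited table. Lower sites fell in 619 genes and higher sites in 20, and 4 genes held both.

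The genic lower site with the smallest p was assigned to the gene body of Vwf by the authors' annotation (mm10, chromosome 6, 125687101 to 125687375). Vwf encodes von Willebrand factor, a clotting protein of endothelial cells, and the site lay 134290 bp from the start of this 133.731 kb gene, past its 3' end in RefSeq. It held 0.277 ± 0.479 normalised counts (SD, n = 3) in susceptible mice and 11.5 ± 1.92 (SD, n = 2) in controls. That rested on 1 susceptible and 33 control reads, a pooled fold of 27.9 with an exact 95% counting interval of 4.67 to 1134. A site at the promoter of Pkn2, a protein kinase gene, lay 709 bp upstream of the start (chromosome 3, 142882526 to 142882900). It fell from 15.2 ± 1.87 (SD, n = 2) to 2.55 ± 2.28 (SD, n = 3). The proximal promoter of Gsn, encoding the actin-severing protein gelsolin (chromosome 2, 35256051 to 35256450), fell from 18.4 ± 2.57 (SD, n = 2) to 3.45 ± 0.621 (SD, n = 3). The authors' deposited table gives log2 fold changes of -5.38, -2.57 and -2.42 for these sites, with adjusted p of 0.000367, 0.000367 and 0.000458. Its enrichment ratios at Pkn2 and Gsn were under 1 in both groups and went the other way. They were 0.73 in susceptible mice against 0.49 in controls at Pkn2, and 0.66 against 0.42 at Gsn. The ratio was also larger in susceptible mice at other lower sites named below. Among them were the Lrp1b site with the smallest p and the sites of Ptprd, Anks1b, Gnal, Foxp1, Unc5d and Stxbp5l. At others, such as those of Vwf, Nsf and Nr3c1, the ratio was smaller in susceptible mice. Over all lower sites the control ratio was at least 1 at 75.7%, which includes 60.3% where it was listed as infinite. The susceptible ratio was at least 1 at 49.1% of the same sites. The other lower sites with the smallest p lay in the gene bodies of Cmtm4, Slc35f1, the cyclin-dependent kinase gene Cdk14, Klhl1 and Itgbl1. They held between 1 and 3 susceptible reads each, against 29 to 37 control reads. The pooled fold was 24.5 at Cdk14 (exact 95% counting interval 4.06 to 1001), 14.4 at Cmtm4 (3.68 to 123), 10.4 at Slc35f1 (3.3 to 52.8) and 10.1 at both Klhl1 and Itgbl1 (3.20 to 51.5).

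Several genes were hit repeatedly, and 67 genes carried 2 or more sites. Lrp1b, a very long gene for an endocytic receptor of the LDL receptor family, had 5 lower sites along chromosome 2 between 40916251 and 41475700. Rbfox1, a neuronal splicing regulator, had 4 lower sites, and the protocadherin gene Pcdh9 had 3. At the Lrp1b site with the smallest p the count fell from 15.7 ± 1.11 (SD, n = 2) to 3.05 ± 2.44 (SD, n = 3), and at the Rbfox1 site with the smallest p from 13.3 ± 0.672 (SD, n = 2) to 2.62 ± 0.847 (SD, n = 3).

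The 31 higher sites had no promoter site among them. The genic site with the smallest p lay in the gene body of Arid1a, a subunit of the SWI/SNF chromatin remodeller (chromosome 4, 133738101 to 133738450). Its count was 14.5 ± 2.46 (SD, n = 3) in susceptible mice and 2.33 ± 1.99 (SD, n = 2) in controls. Zeb1, a zinc finger transcription factor, had 18.5 ± 2.52 (SD, n = 3) against 4.77 ± 1.56 (SD, n = 2), and Cfap221 had 10.3 ± 0.495 (SD, n = 3) against 1.07 ± 1.51 (SD, n = 2). The authors' deposited table gives log2 fold changes of 2.64, 1.96 and 3.27 for these sites, with adjusted p of 0.000564, 0.000896 and 0.00113. Plxdc2, the potassium channel gene Kcnq1, the acetyl-CoA carboxylase gene Acacb, Pamr1 and Fam227b completed the higher group. Plxdc2 and Acacb had wide spreads, 38.0 ± 23.2 and 41.2 ± 26.5 (SD, n = 3), against 12.3 ± 4.61 and 10.7 ± 6.88 (SD, n = 2) in controls. At 10 higher sites, those of Plxdc2, Acacb and Fam227b among them, the susceptible mean was above 20. The authors' deposited table gives these sites enrichment ratios of at most 0.34 in susceptible mice and 0.05 in controls. The ratios at the Arid1a site were also under 1, 0.77 and 0.12. Of all 31 higher sites, 32.3% had a susceptible ratio of at least 1.

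**Figure D1:**
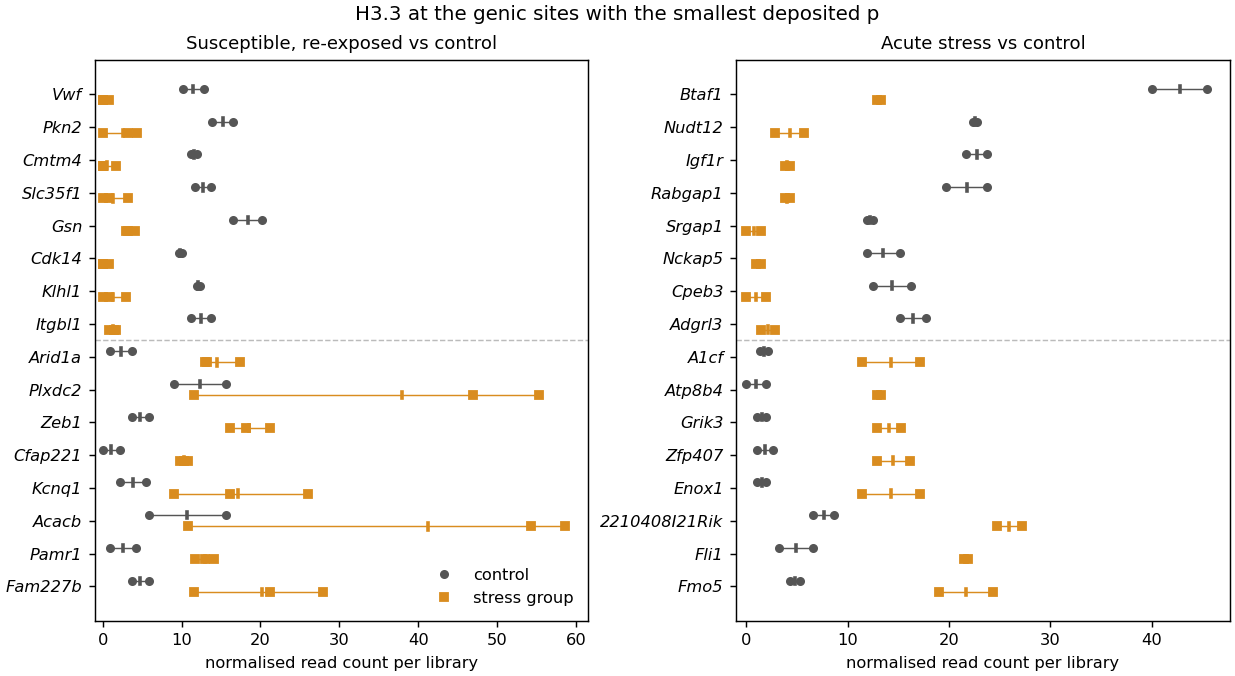
Normalised read count per library (horizontal axis, linear) at the 8 lower (above the dashed line) and 8 higher (below it) genic sites with the smallest deposited p in each comparison, with 1 point per library, a vertical tick at each group mean and a line over the range. At the lower sites every stress library lies below both control libraries, and at Plxdc2 and Acacb 1 susceptible library (11.6 and 10.8) lies inside the control range (9.08 to 15.6 and 5.87 to 15.6).

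Of the fixed lists, synaptic adhesion genes had the most members with a lower site after re-exposure, 23 of 51, among them the neurexin gene Nrxn3, the neuroligin gene Nlgn1, the teneurin genes Tenm2 and Tenm4 and the latrophilin genes Adgrl2 and Adgrl3. These are long genes, and random lists matched on length had 17.6 members with a lower site (95% range 12 to 23, permutation p = 0.101, adjusted p = 1). The sites of the list with the smallest p were in Dscam (10.4 ± 0.417, n = 2, to 0.553 ± 0.958, n = 3, mean ± SD), Ptprd (10.6 ± 0.615 to 1.31 ± 0.423) and Ntm (13.5 ± 1.70 to 1.92 ± 2.09), all in gene bodies. Dscam held 2 susceptible reads (pooled fold 13.1, exact 95% counting interval 3.33 to 113) and Ptprd 3 (8.73, 2.72 to 44.6).

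Presynaptic release genes had lower sites in 8 of 35 members (4.85 expected from length), including the SNARE disassembly factor Nsf, the calcium sensor Syt1 and Stxbp5l. The Nsf site fell from 18.4 ± 1.17 (SD, n = 2) to 4.81 ± 1.79 (SD, n = 3). Glutamate receptors had 7 of 24 (5.29 expected), including the metabotropic genes Grm5, Grm7 and Grm8, with Grik4 and Grin3a. Postsynaptic scaffold genes had 6 of 26 (4.74 expected), including Anks1b, Magi2 and Camk2d. Voltage-gated channels had 7 of 44 (7.90 expected), including the calcium channel genes Cacna1c and Cacnb2. Axon guidance genes had 7 of 41 (7.47 expected), including Unc5d, Epha6 and Nrp1. Neurotrophic genes had 5 of 34 (3.63 expected), including the BDNF receptor gene Ntrk2, Nrg3 and its receptor gene Erbb4.

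Of the genes for stress hormone signalling, the glucocorticoid receptor gene Nr3c1 and the mineralocorticoid receptor gene Nr3c2 had a lower site each, 2 of 21 members (0.671 expected). The Nr3c1 site (chromosome 18, 39437551 to 39437900) fell from 17.4 ± 6.51 (SD, n = 2) to 3.45 ± 0.621 (SD, n = 3), and the Nr3c2 site from 13.8 ± 0.0849 (SD, n = 2) to 2.42 ± 3.01 (SD, n = 3). Medium spiny neuron genes had 4 of 30 (2.74 expected): Ebf1, Foxp1, Meis2 and Gnal, whose product is the G protein that couples dopamine receptors to adenylyl cyclase in the striatum. Chromatin regulators had 5 of 46 (2.77 expected), including Smarca4 and Kmt2e, and Arid1a carried a lower and a higher site at different positions. Of the GABA receptor list, Gphn, encoding the scaffold gephyrin, had a higher site (1 of 15, 0.0542 expected).

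Markers of other cells were also present. Astrocyte genes had 3 of 20 (1.32 expected), namely Gpc5, Slc4a4 and Aldh1l1. Oligodendrocyte precursor genes had 2 of 11 (1.49 expected), Tnr and Pdgfra, and endothelial or mural genes 2 of 18 (0.902 expected), Vwf and Ebf1. No lower or higher site fell in the lists of immediate early genes, striatal interneuron markers, monoamine and peptide receptors, H3.3 with its chaperones, oligodendrocyte markers, microglia or housekeeping genes. Lists without a site had at most 1.05 members expected from length. None of the 21 lists passed the threshold for lower or higher sites (permutation test, adjusted p = 1 for each). With random genes not matched on length, 9 of the 21 passed for lower sites.

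The lower sites lay in gene bodies at 616 positions (49.1%), in promoters at 77, in other intergenic sequence at 362 and in gene deserts at 197. The midpoints of 52.3% of them fell inside a protein-coding gene, against a mean of 40.3% for random positions on the same chromosomes (95% range 37.6 to 43.0%, two-sided permutation p = 0.002, the smallest that 1000 placements can give). Acute lower and higher sites were also above their ranges, at 55.4% (35.7 to 45.0%) and 46.4% (36.4 to 44.9%). The placements took no account of read coverage, so uneven coverage along genes is not excluded. No genomic class differed between higher and lower susceptible sites (smallest adjusted p = 0.514, Fisher exact test). On all 19 autosomes lower sites were the majority (two-sided exact sign test, p = 3.81e-06), though all autosomes come from the same 5 libraries. The exact counting test at 0.0001 kept 1063 lower and 22 higher sites. The sites of Gphn and Pdgfra and 1 site each of Lrp1b, Rbfox1 and Pcdh9 were among those that did not pass it. With any 1 of the 5 libraries left out it kept between 158 and 435 lower and between 6 and 14 higher sites, a lower share of 93.4% to 96.9%. These runs pick among sites already listed, nearly all of them lower, so the share is no test of that majority.

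**Figure D2:**
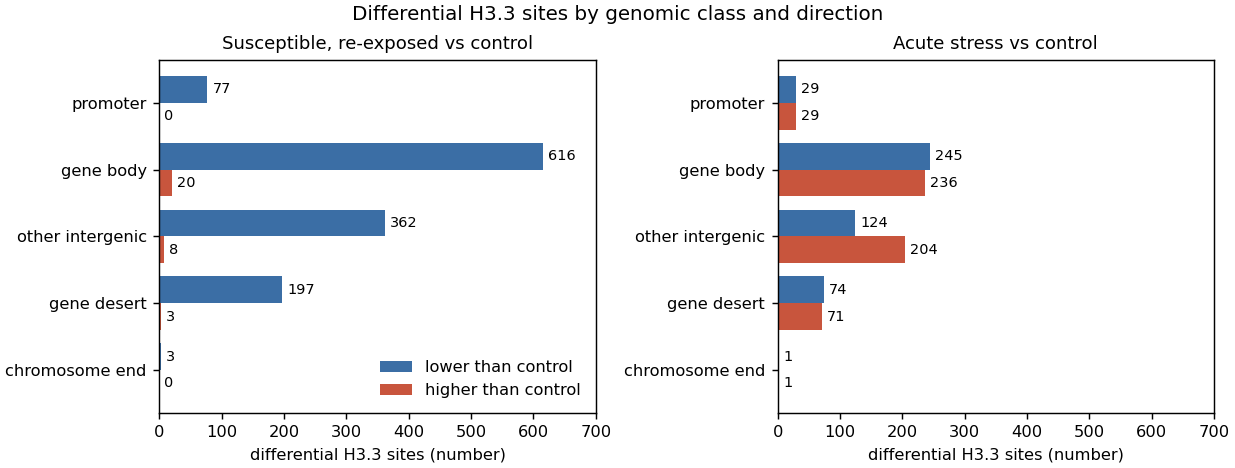
Number of differential H3.3 sites (horizontal axis) in each genomic class of the authors' annotation, lower (blue) or higher (red) than in controls, for each comparison. Gene bodies hold 616 lower and 20 higher sites after susceptible re-exposure and 245 lower and 236 higher sites after acute stress.

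The second comparison asked where H3.3 differed from controls after a single acute stress. Sites went in both directions. The authors' deposited table lists 541 higher and 473 lower sites, a lower share of 46.6% (95% Wilson interval 43.6 to 49.7%). At the higher sites the median of the group means was 15.0 normalised counts after acute stress and 3.26 in controls, and at the lower sites it was 2.38 and 14.4. The median log2 fold change of the lower sites in the authors' deposited table was -2.64. Higher sites fell in 260 genes, lower sites in 259, and 17 genes held both.

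The genic lower site with the smallest p was in Btaf1, encoding an ATPase that removes TATA-binding protein from DNA (chromosome 19, 36942901 to 36943550). Its count fell from 42.8 ± 3.78 to 13.1 ± 0.318 (SD, n = 2 each), on 103 control and 23 acute stress reads, and 2 more lower sites lay in the same gene, 1 of them at its promoter. Nudt12, which encodes a hydrolase of NADH (promoter, chromosome 17, 59011301 to 59011750), fell from 22.5 ± 0.262 to 4.29 ± 2.03 (SD, n = 2 each). Igf1r, the receptor gene of insulin-like growth factor 1, fell from 22.7 ± 1.49 to 4.04 ± 0.346 (SD, n = 2 each). The authors' deposited table gives log2 fold changes of -1.71, -2.39 and -2.49, with adjusted p of 0.00537, 0.00595 and 0.00595. Rabgap1 and Adgrl3 followed, with log2 fold changes of -2.43 and -2.94 in the authors' deposited table, and so did Srgap1, Nckap5 and Cpeb3, an RNA-binding regulator of translation. The last 3 held 1, 2 and 2 acute stress reads, with pooled folds of 21.5 (exact 95% counting interval 3.57 to 876), 12.2 (3.12 to 105) and 12.2 (3.12 to 105).

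The genic higher sites with the smallest p were in A1cf, an RNA-binding cofactor of mRNA editing, and in Atp8b4 and Grik3, the latter a kainate-type glutamate receptor subunit. At Grik3 (chromosome 4, 125604351 to 125604625) the count was 14.0 ± 1.66 after acute stress and 1.52 ± 0.629 in controls (SD, n = 2 each), on 25 and 4 reads. At A1cf it was 14.3 ± 4.01 against 1.74 ± 0.601, and at Atp8b4 13.1 ± 0.318 against 0.985 ± 1.39 (SD, n = 2 each). The Atp8b4 site held 3 control reads (pooled fold 10.7, exact 95% counting interval 3.24 to 55.7). The authors' deposited table gives log2 fold changes of 3.20, 3.04 and 3.73 for Grik3, A1cf and Atp8b4, each with an adjusted p of 0.00689. The enrichment ratios at A1cf were under 1 in both groups, 0.59 after acute stress and 0.13 in controls. Over all acute higher sites the acute stress ratio was at least 1 at 85.0%, which includes 41.0% where it was listed as infinite. The control ratio was listed as infinite at 60.4% of the same sites. Zfp407, Enox1, 2210408I21Rik, the ETS transcription factor gene Fli1 and Fmo5 completed this group, with log2 fold changes from 1.77 to 3.23 in the authors' deposited table.

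By group, synaptic adhesion genes carried lower sites in 11 of 51 members (8.75 expected from length) and higher sites in 4 (6.21 expected). Negr1 fell from 13.1 ± 0.113 to 1.43 ± 2.02 on 32 and 3 reads (pooled fold 7.64, exact 95% counting interval 2.39 to 39.0), and Pcdh15 was higher at 12.8 ± 2.04 against 2.06 ± 0.134 (SD, n = 2 each). Glutamate receptors had 3 of 24 members with a lower site (2.67 expected), including Grik4 and Grm7, and 2 with a higher site (1.99 expected), Grik3 and the NMDA receptor gene Grin2b. Grin2b stood at 13.8 ± 0.693 against 2.73 ± 0.799 (SD, n = 2 each) and did not pass the exact counting test at 0.0001 (p = 0.000115).

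Axon guidance genes had 6 of 41 members with a higher site (2.66 expected, permutation p = 0.0882, adjusted p = 0.926): the ephrin receptor genes Epha3, Epha4, Epha6 and Ephb1, with Dcc and Sema5a. Lower sites of the same list were in 4 (3.69 expected). Epha6 and Dcc carried sites of both directions. In the stress hormone list, the corticotropin-releasing hormone receptor gene Crhr1 and Klf9, a transcription factor gene induced by glucocorticoids, had a higher site, 2 of 21 members (0.221 expected, permutation p = 0.035, adjusted p = 0.735). Crhr1 was at 13.6 ± 3.05 against 2.73 ± 0.799 and Klf9 at 15.2 ± 1.32 against 4.13 ± 0.276 (SD, n = 2 each), and neither site passed the exact counting test at 0.0001 (p = 0.000216 and 0.000235). No member of this list had a lower site.

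Voltage-gated channels had 3 of 44 members with a lower site (3.70 expected) and 3 with a higher site (2.92 expected), including Cacna1e and Scn1a. Medium spiny neuron genes had 2 of 30 in each direction (1.13 and 0.984 expected), and Rarb, a retinoic acid receptor gene, counted in both. Neurotrophic genes had 2 of 34 lower (1.78 expected), Igf1r and Mef2a, and 1 higher (1.25 expected), Nrg3. Postsynaptic scaffold genes had 1 of 26 lower (2.28 expected), Dlg2, and astrocyte genes 1 of 20 lower (0.572 expected), Slc4a4. Higher sites were also found in 1 of 11 oligodendrocyte precursor genes (0.6 expected), Megf11, and in 1 of 37 monoamine and peptide receptor genes (0.402 expected), Crhr1.

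Neither direction had a member in the lists of immediate early genes, striatal interneurons, GABA receptors, presynaptic release (2.04 expected for lower and 1.93 for higher sites), H3.3 with its chaperones, chromatin regulators, oligodendrocytes, microglia, endothelial or mural cells, or housekeeping genes. None of the 21 lists passed the threshold (permutation test, adjusted p = 1 for all with lower sites, and at least 0.735 with higher sites). Lists not matched on length passed in 3 cases for lower and 1 for higher sites.

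**Figure D3:**
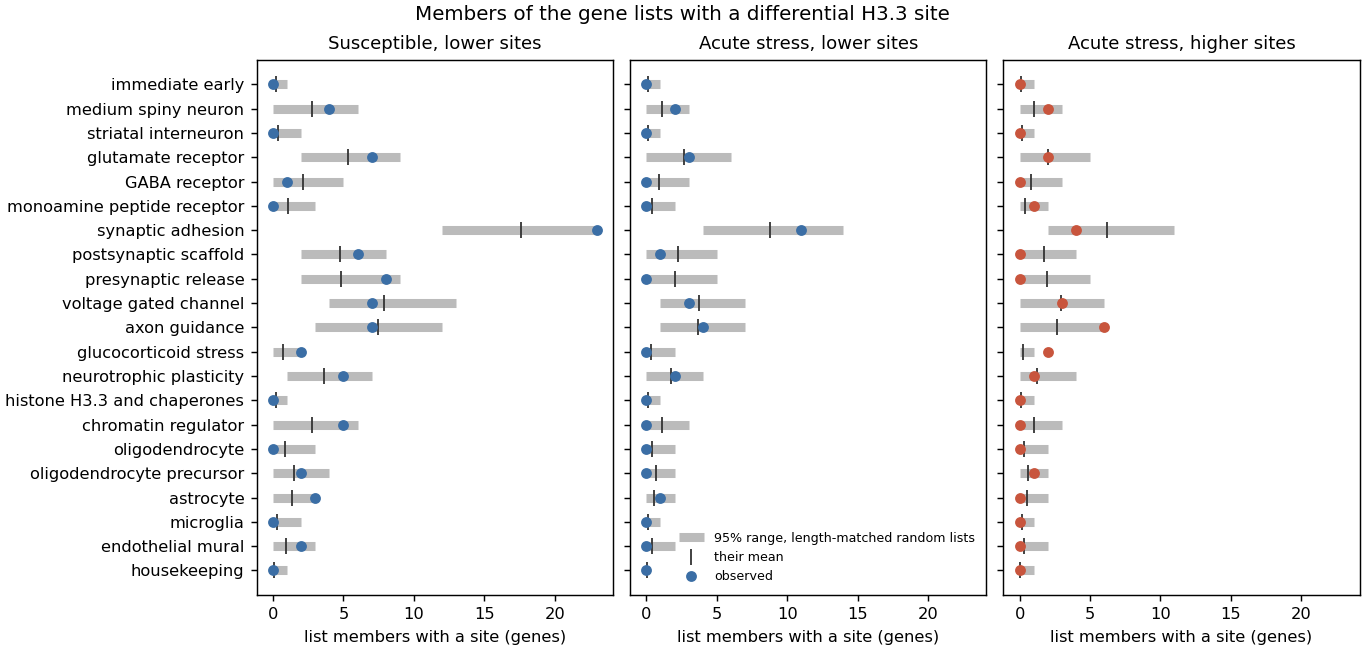
Number of members of each fixed gene list with a differential H3.3 site (points), against the mean (ticks) and the 95% range (grey bars) of random gene lists matched on gene length. Synaptic adhesion genes have 23 members with a lower site after susceptible re-exposure, at the upper end of the range of 12 to 23 for random lists.

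Gene bodies held 51.8% of lower and 43.6% of higher acute sites (Fisher exact test, adjusted p = 0.0245), and other intergenic sequence held 26.2% and 37.7% (adjusted p = 0.000476). At a deposited p of 1e-05 or below neither class passed (Fisher exact test, adjusted p = 1 and 0.894), while other intergenic sequence passed with at least 50 reads and under the counting test (adjusted p = 0.0157 and 0.00554). The majority of higher sites was slight (two-sided exact binomial test, p = 0.0353) and did not pass over chromosomes, with 11 autosomes mostly higher and 6 mostly lower (exact sign test, p = 0.332). With an enrichment ratio of at least 1 in the higher group it was larger, 460 higher and 358 lower sites, with 14 autosomes mostly higher and 4 mostly lower (exact sign test, p = 0.0309). Among the 93 sites with at least 50 reads lower sites were the majority (66.7%), and likewise among the 624 sites past the counting test (59.0%). Among sites past the counting test, the direction of the split changed with the library left out. With all libraries the counting test kept 368 lower and 256 higher sites, and the sites of Dlg2, Megf11 and Nrg3, the higher site of Rarb and 2 of the 3 sites of Epha6 were among those that did not pass it. Without the acute stress library in position 1 or 2 it kept 9 and 29 (23.7% lower) or 48 and 44 (52.2%), and without the control library in position 1 or 2 it kept 99 and 48 (67.3%) or 44 and 3 (93.6%). Leaving out a library changes the relative depth of the groups, and with it the test's power for each direction. These shares therefore cannot tell an unstable split from calls lost mainly in 1 direction.

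The deposited lists differed in direction. The share of lower sites was 50.9 percentage points larger after susceptible re-exposure than after acute stress (Fisher exact test over sites, p = 2.65e-194). It went the same way on 19 of 19 autosomes (exact sign test, p = 3.81e-06). Sites and autosomes come from the same few libraries and are not independent replicates. The difference did not pass with each library left out: among sites past the counting test it was 39.0 points with all libraries and 2.72 points (96.3% against 93.6%, Fisher exact test, p = 0.420) without the control library in position 2, with 44 lower and 3 higher acute sites left. The counting test's power for lower and for higher sites shifts with the library left out, so this does not decide whether the difference is stable. The genomic classes of the sites did not differ between the comparisons (smallest adjusted p = 0.339, Fisher exact test). Presynaptic release genes were 8 of 592 protein-coding genes with a site after susceptible re-exposure and 0 of 473 after acute stress (Fisher exact test, p = 0.0104, adjusted p = 0.218 over the lists).

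Some sites were common to both comparisons. There were 48 overlapping pairs of sites, and in all 48 H3.3 was lower in both. The number was 28 under the counting test, 13 with at least 50 reads per site and 4 at a deposited p of 1e-05 or below, and the comparisons below use the 48. These pairs included sites in Rbfox1, Lrp1b, Epha6, Cacnb2, Adgrl3, Nudt12 and Btaf1. At Cacnb2 (chromosome 2, 14862651 to 14862950) the count was 2.34 ± 1.32 (SD, n = 3) in susceptible mice against 12.5 ± 1.80 (SD, n = 2), and 1.67 ± 0.332 after acute stress against 15.0 ± 1.71 (SD, n = 2 each), the latter on 3 stress reads (pooled fold 8.59, exact 95% counting interval 2.71 to 43.6). Random placement gave a mean of 0.312 overlaps (one-sided permutation p = 0.001, the smallest that 1000 placements can give). The placements took no account of read coverage. Independent lists would share 14.9 lower sites among 39770 regions or 4.18 among 142174, the smallest numbers of tested regions that the adjusted p allow for the susceptible and the acute table. Both lists use the same 2 control libraries and hold only sites selected with both, so how much of the overlap comes from the shared controls is not known.

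At the level of genes, 93 protein-coding genes had a site in both comparisons, against 74.5 for random genes of the same length (95% range 61 to 88, permutation p = 0.0096). Genes with lower sites in both numbered 62 (44.6 for random genes, permutation p = 0.0016), and 26 of these held an overlapping site. The 36 genes without an overlapping site were not above the 44.6 for random genes. An excess of shared genes apart from the overlapping sites was therefore not shown. Genes with higher sites in both numbered 3 (0.933 for random genes, permutation p = 0.127). Random genes do not carry the dependence that the shared control libraries bring, so these p say only that the overlap exceeds that of genes of the same length. Genes lower after susceptible re-exposure and higher after acute stress numbered 35 (35.8 for random genes, permutation p = 0.964). Fli1, the cadherin gene Cdh4 and Trpa1, encoding a sensory cation channel, were of this kind, with the sites at different positions. At Trpa1 the susceptible site fell from 9.85 ± 0.339 (SD, n = 2) to 1.04 ± 0.909 (SD, n = 3) on 29 and 3 reads (pooled fold 8.17, exact 95% counting interval 2.53 to 41.9), and the acute site rose from 2.50 ± 2.60 to 13.3 ± 1.36 (SD, n = 2 each). Pard3, a polarity gene, Sgip1 and Gnaq, a G protein subunit gene, had lower sites at different positions in both.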

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

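Of the tests here, the comparison with the acute list, the fold size and the enrichment ratio were chosen after the results were seen, and the minimum read level was set before. A single result stood out, a difference between the stress conditions under the same contrast with controls: the share of lower H3.3 sites was 50.9 percentage points larger after susceptible re-exposure than after acute stress (97.6% against 46.6%). It did not pass with each library left out: among sites past the counting test it was 39.0 points with all libraries and 2.72 points (Fisher exact test, p = 0.420) without the control library in position 2. The counting test's power for each direction shifts with the library left out, so this does not decide whether the difference is stable.

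Several technical explanations were weighed for the excess of lower sites after susceptible re-exposure. Every higher site had at least 6, 11 and 6 reads in the 3 susceptible libraries, as a minimum read level in each library would give. Every lower site likewise had at least 11 and 18 reads in the 2 control libraries, or 10.1 and 9.61 normalised counts. The control means at lower sites lay close to that level (median 11.8, lower quartile 10.8). Yet 211 lower sites had control means that would clear the minimums of the 3 susceptible libraries by more than 1 counting SD in each, against a bound of 62, 2 times the number of higher sites. The count is past the bound, but the lower sites were listed partly for high control reads, which can raise these means. A minimum may account for part of the excess, and whether it accounts for all of it is not settled. Excess reads in the 2 control libraries cannot be told apart from a change in H3.3. They would make any group set against these libraries mostly lower, and the acute list, with the same control reads, was lower at 46.6% of sites (95% interval 43.6 to 49.7%). That share was 66.7% (56.6 to 75.4%) with at least 50 reads, and by the counting test 93.6% (82.8 to 97.8%) without the control library in position 2 and 23.7% (13.0 to 39.2%) without the acute stress library in position 1, which lie on both sides of the 75% set as the bound. The 2 shares with a library left out also move with the counting test's power for each direction. A scaling error common to the susceptible libraries cannot be told apart either: 16.2% of lower sites had a log2 fold change above -2, but no lower site under a size of 1.61 is listed, so the fold sizes do not decide, and windows that did not change are not in the list. The chronic defeat that the design gives to this group alone stays open and untested.

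A second pattern concerns the higher sites with the most reads in susceptible mice. At 10 of the 10 higher sites with a susceptible mean above 20 (20.2 to 70.3), the enrichment ratio was under 1 in both groups, at most 0.34 and 0.05, and the library in the second position was the lowest of the 3 at all 10. A candidate explanation is that these positions also collect reads in the reference libraries of the ratio; what that reference is was not stated, and no biological explanation was tested. Without them 21 higher sites remain, but low ratios were not confined to the 10. Of all 31 higher sites, 32.3% had a susceptible ratio of at least 1. The Arid1a site (0.77 in susceptible mice and 0.12 in controls) and the Kcnq1 site (0.38 and 0.03) were under 1 in both groups.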

How the results depend on the processing

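The counting test, the enrichment minimum and the separation of libraries were chosen after seeing the data. The alternatives and left-out libraries pick among the sites listed with all libraries, nearly all of them lower in the susceptible list, so they are no test of that majority. Its difference from acute stress passed under the alternatives on listed sites but not with each library left out: among sites past the counting test it was 39.0 points with all libraries, 2.72 (Fisher exact test, p = 0.420) without the control library in position 2, 28.9 without the other control library, and 74.3 and 45.8 without the acute library in position 1 and 2. The counting test's power for each direction changes with the library left out, so these values do not decide whether the difference is stable. The limits on the adjusted p, on the log2 fold change and on chromosomes removed no site and so test nothing, and gene names for intergenic sites are not in the tables. At a deposited p of 1e-05 or below there were 260 lower and 11 higher susceptible sites, 80 lower and 84 higher acute sites (48.8% lower, no longer different from equal shares, exact binomial p = 0.815) and 4 shared sites. With at least 50 reads per site there were 266 and 13 susceptible sites, 62 and 31 acute sites (66.7% lower, a reversed majority) and 13 shared sites. Under the counting test there were 368 lower and 256 higher acute sites (59.0% lower, also reversed) and 28 shared sites. Requiring an enrichment ratio of 1 in the higher group left 950 lower and 10 higher susceptible sites, and 460 higher and 358 lower acute sites (43.8% lower, exact binomial test, p = 0.000407). The causes were not tested beyond the smaller number of sites. In the acute list, higher minus lower sites differed in the share in gene bodies by -0.893 points at p of 1e-05, by -19.4 points with 50 reads and by -9.26 points under the counting test, none past the threshold, and by -8.70 points with the enrichment minimum, past it. In other intergenic sequence they differed by 7.08 points at p of 1e-05, not past the threshold, and past it by 32.3 points with 50 reads, 12.5 under the counting test and 14.3 with the enrichment minimum. Against random genes not matched on length, 9 lists passed for lower susceptible sites, 3 for lower acute sites and 1 for higher acute sites, against 0 in each case with matched genes.

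Leaving out a library lowered the counting test's numbers of 1063 lower and 22 higher susceptible sites to 435 and 14, 171 and 12, and 330 and 12 without the susceptible library in position 1, 2 and 3, and to 258 and 10, and 158 and 6, without the control library in position 1 and 2. The 368 lower and 256 higher acute sites (59.0% lower) became 9 and 29 (23.7%), and 48 and 44 (52.2%), without the acute library in position 1 and 2, and 99 and 48 (67.3%), and 44 and 3 (93.6%), without the control library in position 1 and 2. Directions per site are no test of stability, since the libraries of the 2 groups do not overlap at nearly all listed sites. Of the 70 named susceptible sites, 64 passed this test with all libraries and between 18 and 42 with a library left out, and of the 49 named acute sites 39 passed, and between 3 and 19 with a library left out. With fewer reads the test makes fewer calls by construction, and not equally in both directions. At these depths it recovered 11% and 11.5% of simulated 4-fold changes, so most changes of that size went uncalled at the simulated levels. Those levels lie below the control means of the lower sites, so the shares understate recovery there. No paired analysis was possible because the tables do not say which replicate each value belongs to.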

Other observations

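The test of gene length was set before its result was seen. Beyond the comparisons above, the overlapping sites that were lower in both stress conditions lay in gene bodies at 27 positions, in a promoter at 1, in gene deserts at 12 and in other intergenic sequence at 8. The following genes were picked from these sites after their values were seen. Itch, a ubiquitin ligase gene, held 0.82 ± 0.815 normalised counts (SD, n = 3) in susceptible mice and 1.67 ± 0.332 (SD, n = 2) after acute stress, on 2 and 3 reads against 31 control reads (pooled folds 13.1 and 7.40, exact 95% counting intervals 3.33 to 113 and 2.31 to 37.8). Pde4d, a cAMP phosphodiesterase gene, held 1.80 ± 1.07 (SD, n = 3) and 1.19 ± 0.339 (SD, n = 2), on 4 and 2 reads against 29 (pooled folds 6.13 and 10.4, intervals 2.15 to 24.0 and 2.63 to 89.8). Nalcn, encoding a sodium leak channel of neurons, held 4.25 ± 3.43 (SD, n = 3) and 3.81 ± 1.34 (SD, n = 2), the latter not past the exact counting test at 0.0001 (p = 0.000149). The median log2 fold changes in the authors' deposited table were -2.29 and -2.40 over the 48 sites. These sites had a median of 40 control reads, against 35 at all lower sites of the susceptible list.

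Genes with lower sites after susceptible re-exposure were long. The median length of the protein-coding genes around lower sites was 188.75 kb, above the 95% range of 117 to 164 kb over 200 random placements of the same number of sites. Even spreading along the chromosomes thus does not give this value. The placements took no account of read coverage, so uneven coverage along genes is not excluded. The corresponding values after acute stress were 202 kb for lower and 142 kb for higher sites, against 95% ranges of 110 to 181 kb and 111 to 175 kb. For higher susceptible sites it was 117 kb, inside a range of 60.6 to 324 kb. Only the lower sites were past their ranges, and both sets of lower sites were selected for high reads in the same 2 control libraries. No biological explanation was tested. A hypothesis is that lower H3.3 sites favour long genes, many of them neuronal. The lists matched on length passed no threshold, so a preference for neuronal function beyond length was not shown, and it was not excluded either. Counting sites per kb in long genes with and without neuronal expression would test the hypothesis.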
